A study of Mus musculus and Caenorhabditis elegans with 14 samples.

How the data were processed

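Gene expression was measured by RNA-seq in 14 libraries, 6 from whole adult worms and 8 from mouse embryonic fibroblasts. Per the labels' protocols, polyadenylated RNA was purified, fragmented chemically and reverse transcribed from random hexamers with an Illumina RNA sample preparation kit. The aligner named by the submitters' processing notes is Bowtie and the genome build is mm9, the mouse build, which the notes list for the worm samples too. The worm build, the annotation, the counting program and its use of strand are not given in the sources used here. The fibroblasts were grown in medium with high glucose and serum, per the labels.

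The deposited tables hold whole-number counts of reads, not normalized, per gene and per transcript, one pair of tables per comparison. A gene's count is the sum over its transcripts, so a read that fits several transcripts of a gene can be counted several times. Rows that repeated another exactly were removed, 1539 for worms and 3568 and 3605 for the mouse comparisons. For worms, 1 row had no number and was left out, as were 144 names that are words of a product description and not gene names (1.29 to 1.37% of the counts). This left 26632171 to 29253405 counts per worm library, 17260554 to 20509707 per library of the irs1 comparison and 36991535 to 44436004 per library of the insr comparison. The gene tables also hold 8 columns that matched no sample's labels, and these were not used. Columns of the worm and irs1 tables were matched to samples by the number in the title. Columns of the insr table show the group and a running number that the labels do not give, so they served as replicates of the group without a sample number. The titles of both insr lines carry insr+/-, that of the control with lox and that of the other with knockout, and the genotype label of the control, wild type, conflicts with its title. The control is called the lox control here. Names of mouse genes follow the tables. For gene neighbours and transcripts they were matched to RefSeq symbols of the assembly GRCm38.p6 (88.2% of names tested in the insr comparison). Its start positions were used only to order genes along the chromosomes.

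Each comparison was fitted on its own libraries with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, libraries scaled by TMM, and groups compared with the quasi-likelihood F-test (robust settings) and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. A standard error is the absolute log2 fold change divided by the square root of F. CPM values are counts divided by the TMM-scaled library size, as edgeR scales them. The difference between the irs1 and insr effects was tested in a fit of all 8 MEF libraries. Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 with a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the lists of a comparison, and again with an estimated correlation; fry was run beside it. With an estimated correlation, camera draws on the few residual degrees of freedom of a fit, so a list can lose its call even without correlated genes. The test, the lists and the rule for naming genes were fixed before the data were examined. The rule took the targeted gene, all tested genes of proline metabolism, the 6 largest rises and falls among genes past the threshold with at least 5 CPM on average and groups that do not overlap, up to 3 called members of smallest p from each list, and for the difference of effects the 5 smallest p. The text names genes of that set unless it says otherwise.

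On simulated counts for the real genes, with known changes put in, the worm fit recovered 87.8% of 2-fold and 96.9% of 4-fold changes. The irs1 fit recovered 66.3 and 82.5% and the insr fit 64.6 and 93.9% of changes of these sizes, and the fit of the difference 42.1 and 71.0%. Unchanged genes made up 5.2, 5.8, 7.2 and 12% of the calls. Few genes were changed in these simulations (98 of 13091 at each size in the worm fit), as many up as down. Far more genes differed in the data, so these shares need not hold there. Replicate libraries differed by more than sampling noise (a chi-square per transcript of 3.39 to 32.23, against 1 for sampling alone), so none was counted as a repeat.

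Whether replicate numbers pair libraries was checked from the deviations of log2 CPM from the group means. In worms, libraries with the same number had correlations of 0.19, 0.34 and 0.51, and those with different numbers between -0.43 and -0.04, so the numbers were taken to pair the samples. In the irs1 comparison the labels give same-numbered libraries the same passage, so they were taken as paired by passage. Their correlation was 0.24 and that of different numbers -0.24, which are equal in size by construction with 2 libraries per group. The main fits of both comparisons did not use the pairing. A fit with the number as a block was run as an alternative for both. Other alternatives were DESeq2 size factors in place of TMM, no low-count filter, the Wald test of DESeq2 1.42.0, each library left out in turn, all 8 MEF libraries in a single fit, and an absolute log2 fold change over 1 for overlaps. Counting 1 transcript per mouse gene, the one with the highest total, was added after seeing the data.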

Results

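Polyadenylated RNA was sequenced from nematode worms and from mouse embryonic fibroblasts (MEF, connective tissue cells cultured from mouse embryos). Each comparison set worms or cells labelled as mutant for a gene of the insulin and IGF signalling pathway against controls. Signalling itself was not measured here. The worm part had 3 libraries of wild-type Caenorhabditis elegans (the Bristol strain N2) and 3 of the daf-2(e1370) strain, which carries a mutation in the worm's receptor for insulin-like peptides. All worm libraries came from whole adult animals taken 5 days after the last larval stage. The first MEF comparison had 2 libraries of wild-type cells and 2 of cells labelled as lacking Irs1, the adaptor protein that passes the signal on from the insulin and IGF receptors, each at passages 87 and 89. The second had 2 libraries of a lox line and 2 of a line labelled as a knockout of the insulin receptor gene Insr, at passages 91 and 93. The titles of both lines carry insr+/-, while the genotype label of the lox line is wild type, so the genotype contrast is not settled by the labels. Below, the former is called the lox control and insr+/- cells means the libraries labelled knockout. The counts kept for testing came to 26632171 to 29253405 per worm library. They came to 17260554 to 20509707 per library of the irs1 comparison and 36991535 to 44436004 per library of the insr comparison. The labels do not say whether worm libraries of a group came from separate populations, so their spread may be technical. MEF libraries of a group differ in passage, and the labels do not say whether they came from separately derived lines. In each comparison p-values thus measure only the spread between these libraries, which in MEF includes any effect of passage. The series asks how reduced insulin and IGF signalling acts on the breakdown of the amino acid proline in mitochondria, and each comparison therefore reports genes of proline metabolism after the targeted gene.

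In daf-2(e1370) worms, all 5 measured genes of proline metabolism had higher transcript levels than in wild type. All 16 measured body wall muscle markers were higher too, and all 28 measured germline and oocyte markers were lower, although neither list held its call with an estimated correlation (adjusted p = 0.251 for each). The daf-2 transcript itself stood at 363.4 ± 20.8 CPM (counts scaled to a common library size, SD, n = 3) in wild type and 282.2 ± 5.44 CPM in the mutant, a log2 fold change of -0.37 ± 0.06 (SE, edgeR adjusted p = 9.58e-05). It was lower in each mutant library than in each wild-type library, and since the allele is a point mutation the level of the transcript does not check the genotype. B0513.5, the proline dehydrogenase that starts proline breakdown, rose 1.83-fold (log2 fold change 0.87 ± 0.11, adjusted p = 2.4e-05). The dehydrogenase gene alh-6, whose product carries out the next mitochondrial step to glutamate, rose by a log2 fold change of 0.42 ± 0.07 (adjusted p = 0.000148).

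Genes of the opposite, synthetic direction rose too. M153.1, a pyrroline-5-carboxylate reductase, had the largest change of the list, from 2.23 ± 0.347 to 9.40 ± 0.737 CPM (log2 fold change 2.07 ± 0.15, adjusted p = 2.52e-07). T22H6.2, the synthase that makes the proline precursor from glutamate, rose by 1.46 ± 0.21 on the log2 scale, and C16A3.10, an ornithine aminotransferase, by 0.80 ± 0.06. All 5 also passed when adjusted over the list alone. With a median log2 fold change of 0.87, the list as a whole did not pass the camera test against other genes (adjusted p = 0.152, and 0.551 with an estimated correlation).

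**Figure D1:**
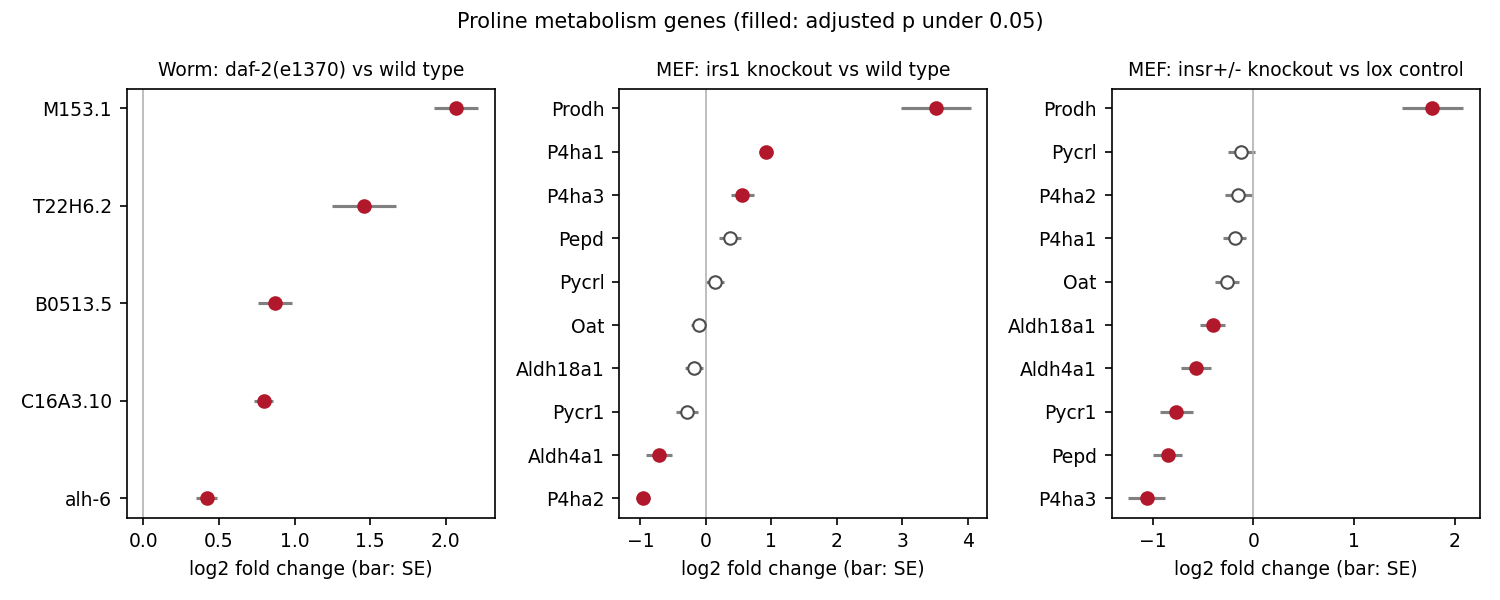
Log2 fold change of genes of proline metabolism in daf-2(e1370) against wild-type worms (3 against 3 libraries), and in MEF for irs1 knockout against wild type and insr+/- knockout against lox control (2 against 2 libraries each). Points are edgeR estimates, bars are standard errors and filled points have an adjusted p under 0.05. The worm genes all lie above 0, and in both MEF panels Prodh lies highest, at 3.51 and 1.78.

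Of 13325 worm genes tested, 11199 differed at an adjusted p under 0.05 (84.0%), 5989 of them higher and 5210 lower in the mutant. Changes over 2-fold were mostly upward, with 4364 genes higher and 499 lower. The largest rises were in genes that were near absent in wild type. D1086.9 went from 0.0606 ± 0.0754 to 105.4 ± 8.07 CPM, F21F3.3 went from 0.0730 ± 0.0632 to 79.2 ± 4.83 CPM, and sod-5, a superoxide dismutase, rose by 6.84 ± 0.27 on the log2 scale. The largest falls were in ilys-5, a lysozyme of the invertebrate type (213.1 ± 53.4 to 4.48 ± 1.32 CPM, log2 fold change -5.57 ± 0.32), C18A3.1 (-3.41 ± 0.13), dod-23 (-3.38 ± 0.10) and the T-box transcription factor gene tbx-38 (-3.33 ± 0.17).

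Genes known from the literature to be induced by DAF-16, the FOXO transcription factor that daf-2 signalling restrains, rose as a list, with 12 of 16 members higher and 3 lower (median log2 fold change 1.79, camera adjusted p = 0.00134, and 0.551 with an estimated correlation). Among them, the mitochondrial superoxide dismutase gene sod-3 rose from 0.803 ± 0.215 to 26.3 ± 1.23 CPM, a 32.4-fold rise, and dod-6 rose by 3.41 ± 0.12 on the log2 scale. The lysozyme gene lys-7 went from 923.6 ± 5.92 to 2089 ± 60.2 CPM. Of 8 measured genes listed as repressed by DAF-16, 3 were higher and 3 lower (camera adjusted p = 0.394). In that list dod-23 fell, whereas dod-17 rose by 3.07 ± 0.21 and dod-19 by 0.75 ± 0.06.

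Tissue markers separated into somatic and germline genes. All 16 body wall muscle markers were higher, with a median log2 fold change of 2.55 (camera adjusted p = 1.27e-17, and 0.251 with an estimated correlation), for example the myosin gene myo-3 (14.3-fold, log2 fold change 3.84), the troponin gene tni-1 (3.72 ± 0.11) and mup-2 (3.07 ± 0.10). Pharynx markers had 9 of 11 members higher and 1 lower (median 2.80, camera adjusted p = 2.33e-08, and 0.251 with an estimated correlation). Neuron markers had 14 of 16 higher and 1 lower (median 1.56, adjusted p = 5.13e-07, and 0.251 with an estimated correlation), among them the synaptic genes snt-1 (2.65 ± 0.09) and unc-13 (2.02 ± 0.08). Hypodermis markers had 9 of 12 higher and 2 lower (median 1.79, adjusted p = 0.000473, and 0.358 with an estimated correlation) and intestine markers 12 of 14 higher and 1 lower (median 1.35, adjusted p = 0.00812, and 0.622 with an estimated correlation). The 28 germline and oocyte markers fell within a narrow range around a median of -0.81 (camera adjusted p = 5.37e-11, and 0.251 with an estimated correlation). They included pos-1, an RNA-binding protein gene of oocytes and early embryos (988.0 ± 4.67 to 488.9 ± 5.47 CPM), the yolk receptor gene rme-2 (-0.89 ± 0.05) and mex-5 (-0.84 ± 0.05). None of 4 sperm markers passed the threshold, and 12 embryo markers split into 6 higher and 5 lower (camera adjusted p = 0.878).

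**Figure D2:**
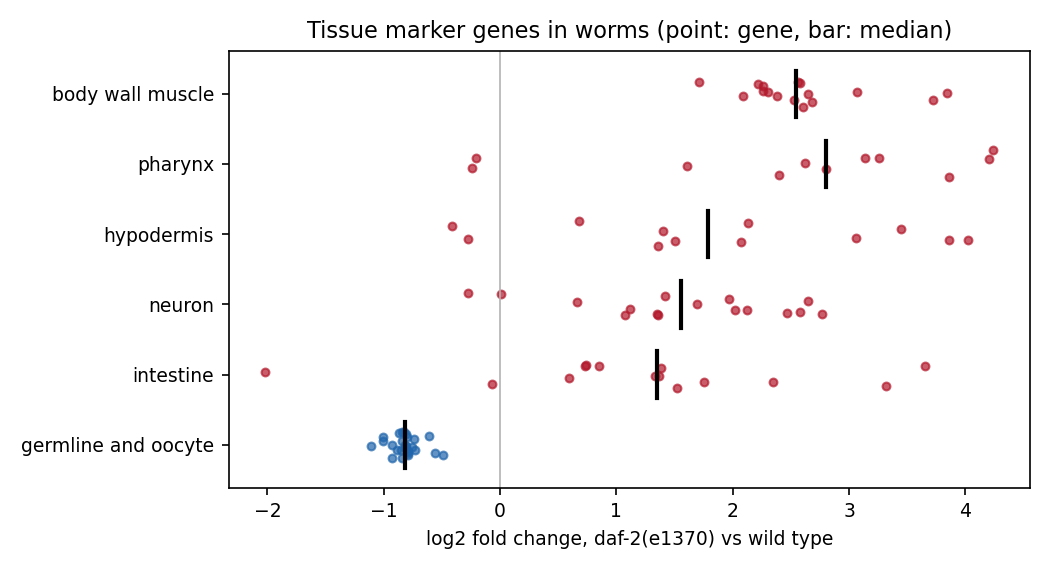
Log2 fold change in daf-2(e1370) against wild-type worms for genes of 6 tissue marker lists, with genes as points and medians as bars. The germline and oocyte markers cluster around a median of -0.81, and the medians of the other lists lie between 1.35 and 2.80.

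The somatic rise and the germline fall stood beside every other worm list, since whole animals were sequenced. Cuticle collagens, the proteins of the worm's outer coat, had 110 of 134 members higher and 4 lower (median 2.94, camera adjusted p = 3.95e-16, and 0.525 with an estimated correlation). The collagen gene dpy-17 rose from 24.9 ± 1.62 to 288.0 ± 27.4 CPM and col-144 by 4.01 ± 0.12 on the log2 scale. Detoxification families rose as well. UDP-glucuronosyltransferases had 47 of 57 higher and 2 lower (adjusted p = 0.00509, and 0.622 with an estimated correlation) and glutathione S-transferases 22 of 31 higher and 4 lower (adjusted p = 0.00967, and 0.525 with an estimated correlation). Among these, gst-42 rose by 2.23 ± 0.11 and ugt-44 by 1.57 ± 0.08. Nuclear hormone receptors had 148 of 196 higher and 13 lower (adjusted p = 0.00812, and 0.551 with an estimated correlation), including nhr-97 (61.7 ± 1.55 to 175.2 ± 1.76 CPM). Cytochrome P450 genes had 37 of 62 higher and 6 lower without passing the list test (adjusted p = 0.0924). C-type lectins (50 of 95 higher, 21 lower, adjusted p = 0.255) and lysozymes and saposin-like peptides (16 of 29 higher, 5 lower, adjusted p = 0.348) did not pass it either.

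None of the following metabolic lists passed the list test without the block. In the list of the glyoxylate cycle, gluconeogenesis and trehalose synthesis, 6 of 9 genes were higher and 2 lower (camera adjusted p = 0.0589, with 0.476 for an estimated correlation and 0.0165 with the replicate number as a block). The trehalose synthase genes tps-1 and tps-2 (log2 fold changes of 1.71 and 1.64) rose, as did W05G11.6, a phosphoenolpyruvate carboxykinase (166.4 ± 25.1 to 1210 ± 128 CPM). Amino acid catabolism had 13 of 15 genes higher and 1 lower (adjusted p = 0.129, with 0.622 for an estimated correlation and 0.0221 with the block), including pah-1, a phenylalanine hydroxylase (1.49 ± 0.08), and hgo-1 of the tyrosine pathway (1.03 ± 0.08). Fatty acid synthesis, desaturation and elongation had 12 of 16 higher and none lower (adjusted p = 0.348), with the desaturase gene fat-6 at 0.96 ± 0.07 and the fatty acid synthase gene fasn-1 at 0.68 ± 0.07. Nuclear-encoded respiratory chain and ATP synthase genes had 17 of 32 lower and 6 higher (adjusted p = 0.262), and the tricarboxylic acid cycle 5 of 9 lower and 2 higher (adjusted p = 0.607). Fatty acid oxidation had 14 of 31 higher and 11 lower (adjusted p = 0.878), and glycolysis 3 of 9 higher and 3 lower (adjusted p = 0.731).

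The other worm lists did not pass the list test. Of 6 vitellogenins, the yolk proteins, 2 were higher and 4 lower (adjusted p = 0.607). The gene vit-6, the most abundant in every worm library, rose from 71970 ± 7720 to 111000 ± 4560 CPM and vit-2 by 0.71 ± 0.10, whereas vit-5 fell by 0.50 ± 0.07 on the log2 scale, a value that is uncertain because its near-identical copies can share reads. Antioxidant enzymes had 7 of 15 higher and 5 lower (adjusted p = 0.307), small heat shock proteins and chaperones 8 of 17 higher and 7 lower (adjusted p = 0.607), and autophagy and lysosome genes 6 of 15 higher and 4 lower (adjusted p = 0.878). The insulin signalling pathway had 5 of 15 higher and 7 lower (adjusted p = 0.781), with the kinase gene akt-2 higher (1.56 ± 0.09) and the lipid phosphatase gene daf-18 lower (-0.83 ± 0.05). AMPK, p38 and SKN-1 regulators had 7 of 14 higher and 6 lower (adjusted p = 0.878). Of 75 cytosolic ribosomal protein genes, 2 were higher and 3 lower (adjusted p = 0.307). No list held its call with an estimated correlation, and 28 of the 32 lists had the same counts when adjusted over the list alone. Those that differed had 2 higher and 2 lower (ribosomal proteins), 13 and 11 (fatty acid oxidation), 7 and 2 (glyoxylate cycle) and 15 and 5 (lysozymes). With DESeq2 size factors the medians of glycolysis (0.08) and insulin signalling (0.04) became -0.02 and -0.06 and that of the chaperones (0.09) became 0. The median, mean and list test differed in sign for 5 lists, namely AMPK, p38 and SKN-1 regulators, antioxidant enzymes, autophagy and lysosome, fatty acid oxidation and insulin signalling.

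Cells labelled irs1 knockout had more transcript of Prodh, the mouse proline dehydrogenase, and of the tumour suppressor gene Trp53 than wild-type cells, and less of the cell cycle inhibitor genes Cdkn2a and Cdkn2b. The targeted gene checks the label only weakly. Irs1 stood at 65.9 and 59.7 CPM in the wild-type libraries and at 48.4 and 46.6 CPM in those labelled knockout, a log2 fold change of -0.40 ± 0.13 (SE, edgeR adjusted p = 0.0227). The transcript was thus 1.32-fold lower and not lost, and without wild-type replicate 1 or 2 its adjusted p was 0.183 or 0.0565 (Irs1 at -0.333 and -0.486, and 0.00815 to 0.183 over all alternatives). The labels do not say which part of the gene was disrupted, and a count over the whole transcript can keep reads from parts that remain. Directions below are those of the libraries as labelled.

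Prodh rose from 0.453 ± 0.198 to 5.25 ± 2.26 CPM (SD, n = 2), an 11.4-fold change (log2 3.51 ± 0.53, adjusted p = 0.000284), at a low level of expression. Aldh4a1, which carries out the next step of proline breakdown, went the other way, from 17.4 ± 0.323 to 10.6 ± 1.62 CPM (log2 -0.72 ± 0.19, adjusted p = 0.0109), although without wild-type replicate 1 or 2 its adjusted p was 0.0617 or 0.0766 (at -0.737 and -0.71, and 0.00127 to 0.0766 over all alternatives). Among the collagen prolyl hydroxylases, P4ha1 rose (0.92 ± 0.11) and P4ha2 fell (-0.96 ± 0.11). P4ha3 was higher (0.56 ± 0.18) and lost its call without wild-type replicate 1 or 2 or knockout replicate 2 (0.55, 0.543 and 0.198, adjusted p = 0.118, 0.128 and 0.242, and 4.18e-07 to 0.242 over all alternatives). Of the other genes of the list, 5 did not pass the threshold, with log2 fold changes of -0.18 for Aldh18a1, -0.11 for Oat, 0.37 for Pepd, -0.29 for Pycr1 and 0.14 for Pycrl. Without knockout replicate 1, Aldh18a1 and Pycr1 passed it as lower (adjusted p = 0.0123 and 0.0164, with up to 0.907 and 0.621 over the other alternatives). In all, 3 genes were higher and 3 lower of 11, with the same counts when adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.955).

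Of 14316 genes tested, 6137 passed the threshold, 3025 higher and 3112 lower in the libraries labelled knockout, and 1752 were more than 2-fold higher and 688 more than 2-fold lower. The cell cycle inhibitor genes Cdkn2a and Cdkn2b were lower, Cdkn2a from 229.1 ± 8.34 to 2.76 ± 0.618 CPM (83.7-fold) and Cdkn2b from 19.2 ± 1.26 to 0.269 ± 0.0308 CPM. Trp53, the gene of the tumour suppressor p53, was 28.7-fold higher in the libraries labelled knockout, where it stood at 302.4 ± 6.30 CPM against 10.6 ± 3.04 CPM in wild type. The list of p53 targets and senescence had 10 of 16 genes higher and 2 lower, or 11 and 2 when adjusted over the list alone (median log2 fold change 0.99, camera adjusted p = 0.0299, and 0.925 with an estimated correlation). Its members that fell were Cdkn2a and Cdkn2b. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, was higher by 3.72 ± 0.32 on the log2 scale (adjusted p = 0.000424), and without knockout replicate 1 or 2 its adjusted p was 0.0639 or 0.0718 (at 3.779 and 3.621, and 9.87e-71 to 0.0718 over all alternatives).

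Sex-linked transcripts separated the cells as well. Xist, the RNA that coats the inactive X chromosome, stood at 3.85 and 8.02 CPM in the wild-type libraries and at 1223 and 1539 CPM in those labelled knockout. Its antisense partner Tsix moved with it (7.74 ± 0.33), and reads of the pair cannot be assigned to a strand here. The Y-linked genes Eif2s3y (log2 fold change -4.63) and Ddx3y (16.9 ± 0.304 to 1.98 ± 0.643 CPM) were lower. The list counted 2 of 6 higher and 4 lower (camera adjusted p = 0.816, with 0.929 for an estimated correlation and 0.00461, upward, with the replicate number as a block). These differences and those in Cdkn2a and Trp53 ran with the genotype label in every library of this comparison.

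**Figure D3:**
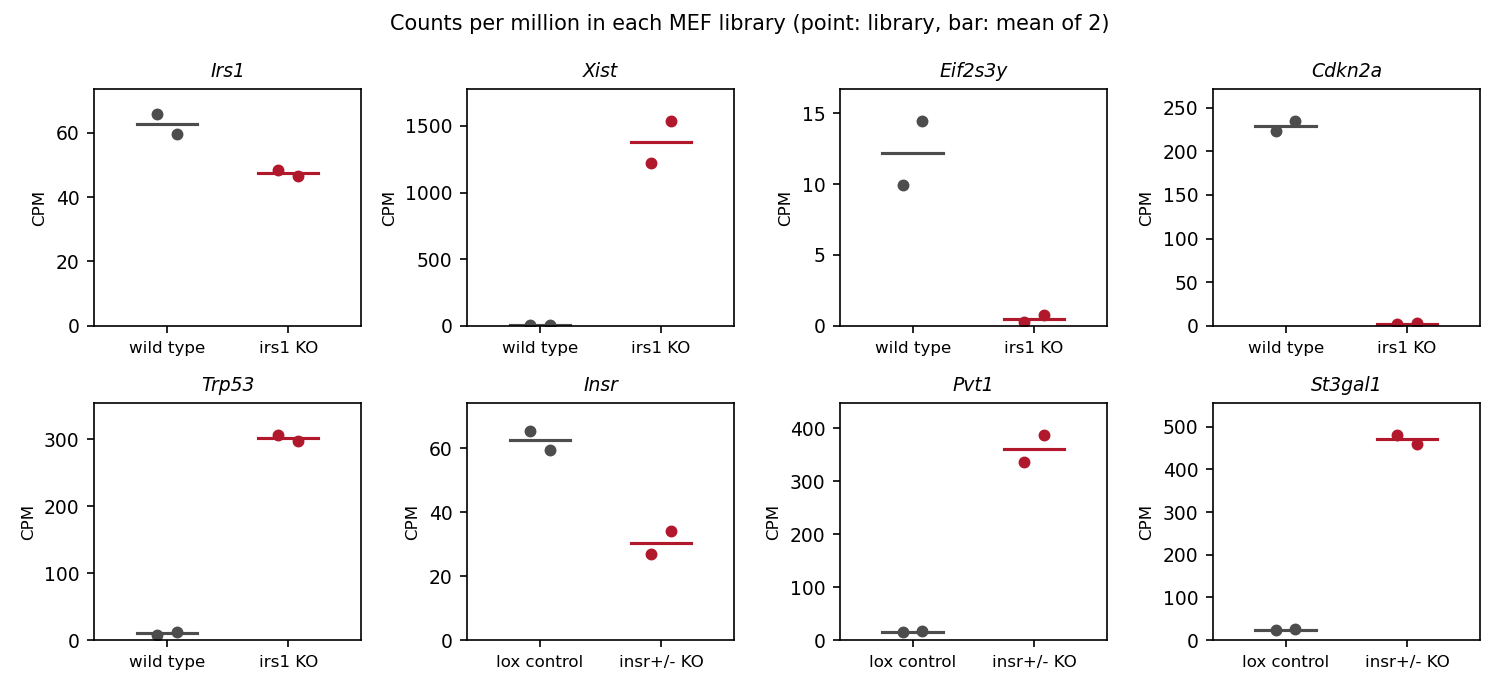
CPM of 8 genes in each MEF library, with libraries as points and the mean of 2 as a bar, for the irs1 comparison (Irs1, Xist, Eif2s3y, Cdkn2a, Trp53) and the insr comparison (Insr, Pvt1, St3gal1). Irs1 fell from 62.8 to 47.5 CPM on average, while Xist, Cdkn2a and Trp53 differed far more between the same libraries.

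Several other genes went from near absence to clear expression, or the reverse. Hoxa11, a limb patterning gene, had no read in wild type and 10.6 ± 1.09 CPM in the libraries labelled knockout, at least 139-fold higher against a floor of 3 counts over the group. Of 30 Hox genes, 12 were higher and 4 lower (camera adjusted p = 0.0598). Dlk1, an imprinted gene that restrains fat cell formation, rose from 4.54 ± 1.26 to 638.7 ± 118 CPM and the retinoic acid binding protein gene Crabp1 from 1.78 ± 0.209 to 168.6 ± 53.8 CPM. Isyna1, which makes inositol from glucose 6-phosphate, fell from 75.1 ± 1.86 to 1.25 ± 0.446 CPM and the chemokine gene Cxcl5 from 45.0 ± 6.87 to 0.730 ± 0.293 CPM. Imprinted genes had 7 of 17 higher and 5 lower, or 8 and 5 when adjusted over the list alone (camera adjusted p = 0.0466, and 0.925 with an estimated correlation), with Peg3 higher (3.92 ± 0.30).

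Basement membrane genes rose as a list, with 7 of 14 higher and 1 lower, or 7 and 2 when adjusted over the list alone (camera adjusted p = 0.000163, and 0.925 with an estimated correlation). Col18a1 rose from 15.9 ± 1.16 to 357.1 ± 0.172 CPM, Lama4 by 1.75 ± 0.12 and Col4a1 by 1.17 ± 0.10. Fatty acid and sterol synthesis had 15 of 24 genes higher and none lower, or 16 and 1 when adjusted over the list alone (camera adjusted p = 0.019, and 0.925 with an estimated correlation), with the cholesterol genes Sqle (0.92 ± 0.12) and Lss (1.04 ± 0.14) among them. The interferon response had 7 of 25 genes higher and none lower (adjusted p = 0.0598, with 0.925 for an estimated correlation and 0.0331 with the block), led by the histocompatibility genes H2-K1 (4.43 ± 1.70 to 85.6 ± 5.37 CPM) and H2-D1 (2.16 ± 0.16), close relatives that can share reads. Glutathione S-transferases had 10 of 15 higher and 2 lower (adjusted p = 0.0598), with Gstt3 higher (1.93 ± 0.25) and Gsta4 lower (-1.49 ± 0.13).

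In the insulin and IGF signalling pathway, 7 of 29 genes were higher and 9 lower (camera adjusted p = 0.533), with the FOXO factor gene Foxo1 lower (42.7 ± 3.43 to 13.9 ± 1.22 CPM), Foxo3 higher (0.97 ± 0.17) and the adaptor gene Gab1 lower (-1.22 ± 0.13). Known FOXO targets had 5 of 21 higher and 4 lower (adjusted p = 0.47), with the kinase gene Pdk4 higher (2.70 ± 0.26) and Sesn3 lower (-1.65 ± 0.22). Of 5 IGF binding proteins, 1 was higher, Igfbp6 (1.47 ± 0.17), and 2 were lower, among them Igfbp3 (-2.27 ± 0.46, list adjusted p = 0.578). Fibrillar collagens and matrix proteins had 6 of 24 higher and 8 lower (adjusted p = 0.652), with Dcn higher (3.55 ± 0.18) and Col12a1 lower (-1.76 ± 0.12). Of 25 tested genes with the symbol stem Col outside the fixed lists, looked up after the data were seen, 15 were higher and none lower (median 1.31, camera adjusted p = 0.037, and 0.974 with an estimated correlation). Matrix proteases and inhibitors had 11 of 18 higher and 6 lower (adjusted p = 0.416), and chemokines and cytokines 8 of 23 higher and 9 lower (adjusted p = 0.412), with Ccl2 higher (1.96 ± 0.12) and Hgf lower (-3.89 ± 0.20). Mesenchymal and fibroblast markers had 6 of 17 higher and 4 lower (adjusted p = 0.9), with Pdgfra higher (1.12 ± 0.11). The adipocyte list had 2 of 11 higher and 4 lower (adjusted p = 0.578), with the regulator gene Pparg lower (log2 fold change -2.82).

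Lists of energy metabolism and growth did not pass. The tricarboxylic acid cycle had 1 of 21 genes higher and 7 lower (adjusted p = 0.412), the nuclear-encoded respiratory chain 16 of 76 higher and 10 lower (adjusted p = 0.703), glycolysis 2 of 19 higher and 6 lower (adjusted p = 0.412), fatty acid oxidation 4 of 21 higher and 6 lower (adjusted p = 0.768), and amino acid catabolism 4 of 26 higher and 7 lower (adjusted p = 0.47). NRF2 targets had 5 of 19 higher and 7 lower (adjusted p = 0.416), with Hmox1 at -2.18 ± 0.12, and antioxidant enzymes 7 of 22 higher and 7 lower (adjusted p = 0.955). Serine synthesis and ATF4 targets had 9 of 23 higher and 3 lower (adjusted p = 0.471), autophagy and lysosome genes 7 of 21 higher and 6 lower (adjusted p = 0.763), cell cycle genes 4 of 32 higher and 12 lower (adjusted p = 0.103) and ribosomal proteins 20 of 84 higher and 7 lower (adjusted p = 0.412). Among lists of other cell types, epithelial (3 of 8), leukocyte (4 of 8), endothelial (3 of 11), neural (3 of 10), contractile (6 of 17), cartilage and bone (1 of 10) and skeletal muscle (1 of 5) markers had the members given in brackets higher, with 0, 0, 2, 2, 2, 5 and 0 lower, and none passed the list test (adjusted p = 0.107, 0.4, 0.533, 0.502, 0.412, 0.412 and 0.578).

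No list of the irs1 comparison held its call with an estimated correlation, and the median, mean and test differed in sign for 10 of the 35 lists. These were proline metabolism, adipocyte markers, amino acid catabolism, antioxidant enzymes, autophagy and lysosome, fatty acid oxidation, fibrillar collagens, IGF binding proteins, insulin and IGF signalling and mesenchymal markers. Adjusted over the list alone, 24 lists had the same counts. Besides those given above, the counts of higher and lower genes became 8 and 7 for autophagy, 4 and 13 for cell cycle, 9 and 10 for chemokines, 7 and 2 for contractile genes, 19 and 5 for ribosomal proteins, 4 and 0 for epithelial markers and 6 and 9 for fibrillar collagens. Without wild-type replicate 1 or 2 the count of genes past the threshold dropped to 3852 and 3723.

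In insr+/- cells, Prodh was higher than in the lox control and 5 other genes of proline metabolism were lower. Of 27 interferon response genes 11 were lower, as were 11 of 24 fibrillar collagen and matrix genes, with none higher in either list, and both list calls were lost with an estimated correlation (adjusted p = 0.837 for each). The targeted gene Insr stood at 65.4 and 59.5 CPM in the control libraries and at 26.9 and 34.0 CPM in the knockout libraries, 2.05-fold lower (log2 -1.04 ± 0.15 SE, edgeR adjusted p = 0.000486). Prodh rose from 1.24 ± 0.0600 to 4.27 ± 0.191 CPM (SD, n = 2), a 3.43-fold change (log2 1.78 ± 0.30, adjusted p = 0.00173). The genes that fell were P4ha3 (-1.06 ± 0.18), Pepd, a peptidase that frees proline from dipeptides (-0.85 ± 0.14), the proline-synthesis reductase gene Pycr1 (-0.77 ± 0.17), Aldh4a1 (-0.57 ± 0.15) and Aldh18a1, the synthase of the proline precursor (-0.40 ± 0.13).

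Some of these genes no longer passed the threshold when a library was left out, which leaves a group with 1 library, while their directions stayed. Libraries are named here by the authors' running numbers. Pycr1 had a log2 fold change of -0.697 without knockout library 28 (adjusted p = 0.115, and 4.46e-09 to 0.115 over all alternatives). Aldh4a1 had -0.449 without control library 27 (0.0788), -0.595 without knockout library 28 (0.108) and -0.592 without knockout library 30 (0.0938), with 0.000557 to 0.108 over all alternatives. Aldh18a1 had -0.305, -0.534 and -0.324 without the same libraries (0.137, 0.0907 and 0.295), with 0.00118 to 0.295 over all alternatives. Oat, P4ha1, P4ha2 and Pycrl did not pass the threshold, with log2 fold changes of -0.27, -0.19, -0.15 and -0.12. In all, 1 gene of the list was higher and 5 lower of 11, with the same counts when adjusted over the list alone (median -0.26, camera adjusted p = 0.104).

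Of 14707 genes tested, 3351 passed the threshold, 1399 higher and 1952 lower, and 329 were more than 2-fold higher and 819 more than 2-fold lower. Without knockout library 28 or 30 the count was 1223 or 1647. The largest rises were Dlk1 (1.09 ± 0.232 to 48.2 ± 2.48 CPM), Srpx2 (0.984 ± 0.189 to 22.2 ± 3.91 CPM), the noncoding RNA gene Pvt1 (4.49 on the log2 scale, 22.5-fold) and the sialyltransferase gene St3gal1 (4.25 on the log2 scale). Myc, the neighbour of Pvt1, was also higher (log2 fold change 1.70), a gene looked up after the values of Pvt1 were seen. The largest falls included Isyna1 (28.7 ± 1.28 to 0.601 ± 0.150 CPM), the choline transporter gene Slc5a7 (54.5 ± 9.36 to 1.23 ± 0.115 CPM), Arhgap36 (-5.16 ± 0.38) and the T-box gene Tbx20 (-4.77 ± 0.17). Imprinted genes had 3 of 13 higher and 2 lower (camera adjusted p = 0.000287, and 0.67 with an estimated correlation), with Dlk1 and Snrpn (4.39 ± 0.403 to 54.6 ± 2.00 CPM) higher. Snurf, which shares its transcript with Snrpn, rose by 3.89 ± 0.21.

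Lists of the extracellular matrix passed the list test as lower, although many of their members did not pass on their own. Of 23 tested genes with the symbol stem Col outside the fixed lists, looked up after the data were seen, 3 were higher and 3 lower (median 0.43, camera adjusted p = 0.576, and 0.971 with an estimated correlation). Fibrillar collagens and matrix proteins had 11 of 24 members lower and none higher (median -0.74, camera adjusted p = 5.02e-06, and 0.837 with an estimated correlation), for example Col1a1 (6202 ± 2010 to 1131 ± 59.3 CPM), Col6a1 (1027 ± 317 to 237.0 ± 1.56 CPM) and Col11a1 (-4.30 ± 0.30). Basement membrane genes had 3 of 14 lower and none higher (adjusted p = 1.13e-05, and 0.67 with an estimated correlation), among them Col18a1 (349.4 ± 16.9 to 35.1 ± 0.373 CPM) and Col4a6 (-4.25 ± 0.17). Cartilage and bone markers had 5 of 10 lower and none higher, or 7 and 1 when adjusted over the list alone (adjusted p = 0.000287, and 0.67 with an estimated correlation). They included Col2a1 (489.4 ± 59.5 to 122.0 ± 18.2 CPM) and its activator Sox9 (-1.53 ± 0.14). Mesenchymal and fibroblast markers had 7 of 17 lower and 2 higher (adjusted p = 0.00145, and 0.696 with an estimated correlation), with Pdgfra (196.0 ± 18.5 to 21.8 ± 0.774 CPM), Thy1 (-4.41 ± 0.45) and Prrx1 (-1.27 ± 0.15) lower. Matrix proteases and inhibitors had 5 of 16 lower and 1 higher (adjusted p = 0.0483, and 0.896 with an estimated correlation).

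The interferon response had 11 of 27 genes lower and none higher, or 19 lower when adjusted over the list alone (median -1.88, camera adjusted p = 1.65e-06, and 0.837 with an estimated correlation), with H2-D1 (31.2 ± 5.66 to 8.30 ± 1.71 CPM) and H2-K1 (-2.29 ± 0.23) among them. Glutathione S-transferases had 7 of 15 lower and none higher (adjusted p = 7.96e-05, and 0.67 with an estimated correlation), with Gstt1 from 73.8 ± 25.8 to 11.3 ± 0.536 CPM and Gsta4 at -2.35 ± 0.16. NRF2 targets had 7 of 19 lower and none higher, or 8 and 1 when adjusted over the list alone (adjusted p = 0.0172, and 0.67 with an estimated correlation). The list of p53 targets and senescence had 5 of 17 lower and none higher, or 9 and 1 when adjusted over the list alone (adjusted p = 0.0124, and 0.67 with an estimated correlation), with Cdkn2c at -1.48 ± 0.16. Fatty acid oxidation had 9 of 21 lower and 2 higher (adjusted p = 0.0445, and 0.67 with an estimated correlation), including the carnitine transferase gene Cpt1a (-1.09 ± 0.15) and the coactivator gene Ppargc1a (-1.19 ± 0.20). Serine synthesis, one-carbon metabolism and ATF4 targets had 9 of 23 lower and 2 higher, or 11 and 2 when adjusted over the list alone (adjusted p = 0.0439, and 0.878 with an estimated correlation), with Shmt1 higher (1.18 ± 0.18).

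The other lists of the insr comparison did not pass. Known FOXO targets had 4 of 21 lower and 1 higher, Pdk4 (2.70 ± 0.25, list adjusted p = 0.183). The insulin and IGF signalling pathway had 3 of 29 higher and 2 lower, Insr among the latter (list adjusted p = 0.923). The growth factor gene Igf2 was among those higher (edgeR adjusted p = 0.00242), with a log2 fold change of 4.299 without knockout library 28. Glycolysis had 6 of 19 higher and 3 lower (adjusted p = 0.412), with the regulator gene Pfkfb3 higher (110.1 ± 32.8 to 305.4 ± 27.1 CPM) and Hk1 lower (-0.88 ± 0.12). The tricarboxylic acid cycle had 1 of 21 higher and 2 lower (adjusted p = 0.98), the respiratory chain 2 of 76 higher and 8 lower (adjusted p = 0.412), amino acid catabolism 2 of 26 higher and 5 lower (adjusted p = 0.772) and fatty acid and sterol synthesis 1 of 24 higher and 3 lower (adjusted p = 0.786). Cell cycle genes had 5 of 32 higher and 4 lower (adjusted p = 0.699), with Ccnd1 lower (-0.83 ± 0.12) and Ccne1 higher (0.97 ± 0.16). Chemokines and cytokines had 7 of 25 higher and 4 lower (adjusted p = 0.699), ribosomal proteins 4 of 83 higher and 3 lower (adjusted p = 0.613), autophagy and lysosome genes 7 of 21 lower and none higher (adjusted p = 0.113), antioxidant enzymes 3 of 23 lower and none higher (adjusted p = 0.895), and Hox genes 1 of 22 higher and 3 lower (adjusted p = 0.895). Adipocyte markers had 3 of 12 lower and 1 higher (adjusted p = 0.135), with Pparg at -1.95 ± 0.20. The endothelial, epithelial, leukocyte, neural, contractile and skeletal muscle lists held 1, 0, 1, 0, 4 and 0 higher and 1, 0, 0, 3, 4 and 1 lower genes, with adjusted p = 0.978, 0.603, 0.412, 0.23, 0.895 and 0.677. Xist was 2.41-fold higher in the insr+/- cells (226.6 ± 2.48 to 546.5 ± 50.8 CPM), and 2 of the 3 tested sex-linked genes, Xist and Tsix, passed the threshold. Of 4 IGF binding proteins 1 was lower, Igfbp6 (-1.27 ± 0.14). No list held its call with an estimated correlation, and the median, mean and test differed in sign for chemokines, contractile genes and insulin and IGF signalling. Adjusted over the list alone, 18 of the 35 lists had the same counts. Besides those given above, the counts of higher and lower genes became 3 and 7 for mesenchymal markers, 1 and 6 for matrix proteases, 1 and 7 for FOXO targets, 7 and 4 for glycolysis, 0 and 0 for the tricarboxylic acid cycle, 0 and 3 for the respiratory chain, 0 and 1 for fatty acid and sterol synthesis, 7 and 7 for chemokines, 0 and 0 for ribosomal proteins, 1 and 4 for adipocyte markers, 1 and 4 for neural markers and 6 and 5 for contractile genes. With DESeq2 size factors the median of the chemokines (0) became -0.01.

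The MEF comparisons used different control cells, so their calls could be set side by side. Of 13825 genes tested in both, 465 were called in the same direction and 1349 in opposite directions. The count higher in both was 183, where independent lists would give 281, and the count lower in both was 282, where independent lists would give 419. Genes higher with irs1 knockout and lower in insr+/- cells numbered 772 (394 if independent), and those lower and higher numbered 577 (300 if independent). Among changes over 2-fold, all 4 combinations exceeded the independent count, at 59 (33.5), 78 (35.5), 259 (89.0) and 40 (13.4) in the same order. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of -0.06 and a Spearman rho of -0.09.

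Genes that moved the same way in both included Isyna1 and Dlk1, which fell and rose furthest by the smaller of the changes in the 2 comparisons, Pdk4 (2.70 in each) and Pparg, Ncam1 and Gsta4, which were lower in each. Genes that moved in opposite ways included Col18a1 (4.49 and -3.31), Pdgfra (1.12 and -3.17), H2-K1 (4.26 and -2.29), Gstt3 (1.93 and -1.73) and Hk1 (0.87 and -0.88). In a fit of all 8 MEF libraries the log2 fold changes of the 2 comparisons differed for 5650 of 15423 genes. Of these, 2939 had the more positive change in the irs1 comparison and 2711 in the insr comparison. Such effects hold any difference between the cells compared, not that of genotype alone. For Isyna1 the difference between the effects was -0.33 ± 0.35 (adjusted p = 0.49) and for Pdk4 it was 0.02 ± 0.38 (adjusted p = 0.978). For Dlk1 it was 1.69 ± 0.31 (adjusted p = 0.000884).

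**Figure D4:**
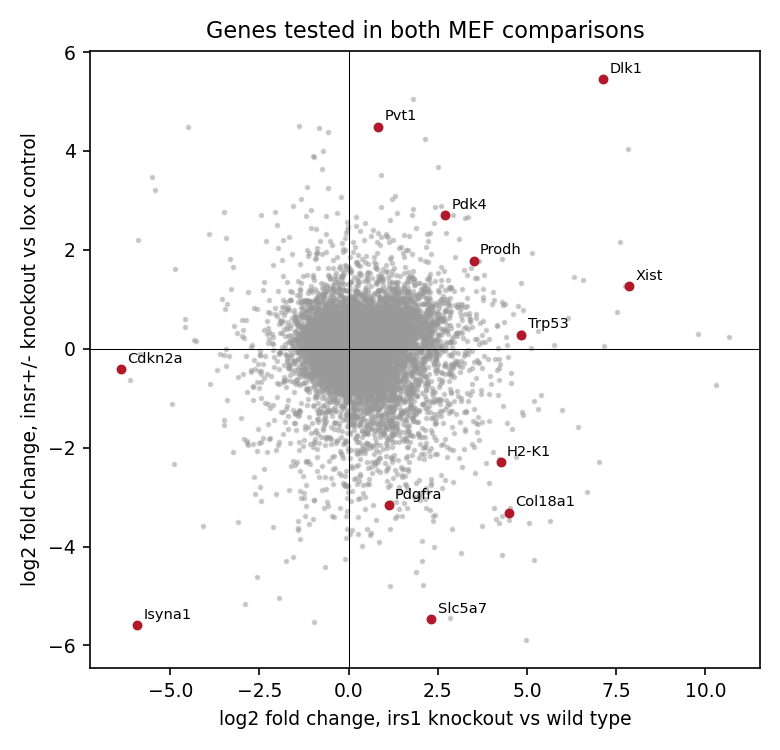
Log2 fold change of each gene tested in both MEF comparisons, irs1 knockout against wild type on the horizontal axis and insr+/- knockout against lox control on the vertical axis, with 12 genes of the text named. Isyna1 lies at -5.92 and -5.58 and Dlk1 at 7.13 and 5.46, while Col18a1 lies at 4.49 and -3.31.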

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

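The tests of the different rise of somatic tissues, of library scaling, of embryo sex, of carry-over, of an unbroken segment and of St3gal1, Ndrg1 and Pvt1 in the irs1 comparison were chosen only after the values concerned had been seen. The irs1 and insr comparisons differed, by a test of the difference itself, for 5650 genes. The 5 with the smallest p were Col18a1 (irs1 change minus insr change 7.81 on the log2 scale), Pogk (6.42), Sema5a (5.95), Crabp2 (6.26) and Lass4 (5.79). Xist (6.61), Cdkn2a (-5.97) and Trp53 (4.57) differed as well. The cells compared may differ in more than genotype, so this does not test the genotypes alone. In proline metabolism the comparisons differed for P4ha1 (1.12), P4ha2 (-0.80), P4ha3 (1.63), Pepd (1.23) and Prodh (1.75). The Prodh difference (adjusted p = 0.0361) did not pass without wild-type replicate 2 (0.151), irs1 knockout replicate 2 (0.135), lox control library 27 (0.0638) or insr+/- library 28 or 30 (0.0962 and 0.104), and ranged from 0.0103 to 0.151 over all alternatives.

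In daf-2(e1370) worms, all 28 germline and oocyte markers were lower and most markers of 5 somatic tissues higher (16 of 16 for muscle to 9 of 12 for hypodermis), with exceptions such as cpr-1 (-2.02) and nhr-23 (-0.41), and no list held its call with an estimated correlation (lowest adjusted p = 0.251). Scaling shifts all lists by one amount, whereas the muscle and germline medians lay 3.36 apart on the log2 scale, against summed quartile ranges of 0.46. This gap is part of the pattern and shows only that the lists moved apart. It does not tell where 0 lies, and so whether germline transcripts fell or somatic ones alone rose. A lower share of germline RNA alone would raise somatic genes alike only where they are not also expressed in the germline. The medians of 5 somatic lists spanned 1.45, more than random allocation of their 69 genes gave (permutation p = 0.037, 10000 permutations). This does not decide the point, since the permutation treats genes as independent. The lists also held genes that did not rise, such as unc-119 (0.01), snb-1 (-0.28) and lin-26 (-0.28), whose germline expression was not measured. Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave as many genes by edgeR, 11199 against 0 in the highest other (0 to 62 at an unadjusted p under 0.05), also among the 3 other splits that part all pairs, but 10 splits are too few for a share under 0.05. A lower share of germline RNA and different changes of separate tissues may each underlie the pattern together with the genotype. These hypotheses are left open here, since tissue amounts and transcript levels within tissues were not measured apart.

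In the irs1 comparison, sex-linked genes and the Cdkn2a and Cdkn2b pair differed between the cell lines. A single mixed-up library is argued against by Xist, which was 152.6 times higher in the lowest knockout library than in the highest wild-type library, and by 4 Y-linked genes summed, which were 10.8 times higher in the lowest wild-type than in the highest knockout library. Embryos of different sex cannot be told apart from other differences between the lines, since the Y-linked genes, which kept at most 11.8% of their wild-type level (Ddx3y), are themselves the pattern. Complete loss of the DNA that holds Cdkn2a and Cdkn2b cannot be told apart from low expression: each knockout library had at least 5 reads of each gene, over the limit of 3 set before the count was seen. That limit left out carry-over of reads between libraries, which at the share Cdkn2a kept (1.2% of wild type, 1.4% for Cdkn2b) is not excluded. Only 3 tested genes had fewer knockout reads than it would give. The lowest p among them was that of Kdm5d, at 0.656% of wild type (2 reads against 3.3 expected, exact Poisson test, p = 0.35), too few reads to decide.

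In insr+/- cells, Pvt1 and St3gal1 were higher by 4.49 and 4.25 on the log2 scale. Reads shared with paralogs of St3gal1 are argued against by the 3 tested paralogs, with a median of -0.27. A gain of the segment that holds Pvt1 stays open as an account of its rise. Of its 10 neighbours on each side only 3 were tested, 9930014A18Rik (0.11), A1bg (5.24) and Myc (1.70). Their median of 1.70 is thus the value of Myc. It lay above the middle 95% of 37519 such windows (-0.68 to 0.68). Windows with more tested genes vary less, so this position does not decide the question. An unbroken gain from Pvt1 to St3gal1 is argued against by the 4 genes between them that average at least 5 CPM, with a median of 0. Asap1 (0.07), Efr3a (-0.11) and Phf20l1 (-0.07) stayed near 0 and Ndrg1 (2.71) did not. Over all 10 tested genes between them the median was 0.49. Past the threshold, 2 of these were higher, Ndrg1 and Tg (1.75), and 0 lower. St3gal1, Ndrg1 and Pvt1 were also higher in the irs1 comparison (log2 fold changes of 2.13, 1.77 and 0.83, with St3gal1 at adjusted p = 0.00612, 0.0537 without wild-type replicate 1 and 1.55e-23 to 0.0352 without the others), so separate gains in the insr+/- line and regulation of these genes stay open.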

How the results depend on the processing

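Counting 1 transcript per gene was the only alternative chosen after seeing the data. Counts of genes past the threshold stayed within 1.5 times under every alternative in worms (10731 to 12007) and for the difference of effects (4342 to 6056). They did so in both MEF comparisons too, except when a library was left out, which leaves a group with 1 library whose spread is assumed to be that of the other group. The irs1 count then ran from 3723 to 6482 and the insr count from 1223 to 4828, with fewer libraries in the fit. With changes over 2-fold required, which by construction keeps fewer genes, the MEF overlap was 137 genes in the same and 299 in opposite directions. With an estimated correlation, 0 lists passed by camera in each of the 3 comparisons, in place of 11, 4 and 12 (4, 1 and 1 at an unadjusted p under 0.05). That setting has little power with so few libraries, so a lost call does not by itself argue against a list. Basement membrane genes in the irs1 comparison had an estimated correlation of -0.068, under the preset 0.01. Their camera adjusted p still went from 0.000163 to 0.925. Other lists had estimates far above the preset, among them the interferon response (0.911) and fibrillar collagens (0.714) in the insr comparison. Worm body wall muscle markers had 0.527 and p53 targets in the irs1 comparison 0.378. For such lists the p with the preset correlation may be too small. With the replicate block, the counts of genes were 11474 in worms, 7092 for irs1 and 5968 for the difference, 13 worm lists and 6 irs1 lists passed in place of 11 and 4, and apart from the lists named with their blocked p it changed no other call of a named gene or list. No paired analysis was possible for the insr comparison because its columns carry no sample number. The fry test asks whether a list changed at all, not whether it changed more than other genes. In the insr comparison the interferon and fibrillar collagen lists did not pass it (fry adjusted p = 0.253 each), and imprinted genes did (0.0431). In the irs1 comparison basement membrane genes passed (0.00533) and p53 targets did not (0.0777). In worms, where 84% of genes were called, the muscle, germline and proline lists passed (5.03e-05, 1.35e-05 and 0.000178). Among the genes named here, directions turned for proline genes that did not pass the threshold: Pycrl without irs1 knockout replicate 2 (-0.01, and 0.255 without replicate 1) and P4ha2 without lox control library 27 (0.009, and -0.343 without 29). DESeq2 size factors turned no list median that had passed and no gene named here, and moved the median of all worm genes by -0.10. Depth limits the low genes: without the filter more genes were tested (18746 in worms), and Prodh rests on 6 to 12 reads per wild-type library.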

Other observations

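The tests of gene families and of the shortened p53 list in this part were chosen after the data were seen. Results of fixed lists are repeated beside them. Worm genes outside the fixed lists were grouped by the stem of their symbol, giving 74 families with at least 10 tested genes, of which 37 passed the camera test with the preset correlation and none with an estimated one (lowest adjusted p = 0.248). Examples of families that were higher in daf-2(e1370) worms follow. Ligand-gated ion channels (lgc) had 32 of 33 members higher and none lower (median log2 fold change 2.23, adjusted p = 2.92e-05, and 0.248 with an estimated correlation), two-pore-type potassium channels (twk) 29 of 32 (median 1.63, adjusted p = 0.000176, and 0.278), and FMRFamide-like neuropeptides (flp) 28 of 28 (adjusted p = 0.00874, and 0.547). Patched-related proteins (ptr) had 19 of 22 higher and 1 lower (median 2.06, adjusted p = 3.37e-07, and 0.248), cuticlin-like proteins (cutl) 24 of 26 higher and none lower (median 2.49, adjusted p = 2.92e-05, and 0.328) and transthyretin-related proteins (ttr) 36 of 45 higher and 3 lower (median 1.35, adjusted p = 2.92e-05, and 0.328). The stems lec (9 of 11 higher, 1 lower, adjusted p = 0.00013, and 0.248), glb (25 of 28 higher, 1 lower, adjusted p = 0.0307, and 0.248) and pqn (34 of 59 higher, 17 lower, adjusted p = 0.000268, and 0.371) passed with the preset correlation too.

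Other families were lower. All 22 nuclear pore genes (npp) fell, with a median of -0.77 (adjusted p = 1.82e-07, and 0.248 with an estimated correlation), as did all 11 proteasome regulatory subunits (rpn, median -0.64, adjusted p = 0.000292, and 0.248) and all 17 TFIID subunits (taf, median -0.71, adjusted p = 0.000361, and 0.248). Not all families of broadly used genes were lower: of 75 cytosolic ribosomal protein genes 2 were higher and 3 lower, and of 18 vha genes 15 were higher and 2 lower (adjusted p = 0.187). In MEF, 12 of 12 genes of the gamma protocadherin A group (Pcdhga), which share their last exons and so their reads, were higher with irs1 knockout (median 1.02, adjusted p = 1.68e-11, and 0.974 with an estimated correlation). In insr+/- cells 12 of 13 alpha protocadherins (Pcdha), which share last exons likewise, were lower (median -1.57, adjusted p = 0.000439, and 0.971). Proteasome subunits of the Psmd family had 11 of 14 lower with irs1 knockout (median -0.74, adjusted p = 0.000256, and 0.974).

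Trp53 and targets of p53 were higher in the libraries labelled irs1 knockout than in wild type, while Cdkn2a was lower. A hypothesis is that p53 activity may have been lower in the wild-type line, and it stays open. Without Trp53, Cdkn2a and Cdkn2b the fixed list had 13 tested genes, 9 higher and none lower, with a median of 1.07, but these are the genes that showed the pattern, so the value does not test the hypothesis. The full fixed list lost its call with an estimated correlation (camera adjusted p = 0.925).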
